A study of Mus musculus with 67 samples.

How the data were processed

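Liver RNA from mice of the Sestrin DKO line and from wild-type (WT) mice was sequenced after feeding with a control or a leucine-free diet for 24 hours (day 1) or 8 days (day 8). The labels give 67 libraries in 8 groups, each library from a separately numbered mouse. Per the labels' protocols, livers were flash frozen, RNA was extracted with a miRNeasy kit, and directional libraries were made with the NEBNext Ultra II kit.

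The values used are raw counts per Ensembl gene, 1 whole number per gene and library, as the authors deposited them. The submitters' processing notes name STAR 2.7.1a, featureCounts 2.0.1 and DESeq2 1.26.0 and the builds GRCm38 and mm10, without saying which step each served; the strand setting of the counting is not given in the sources used here. All 55450 gene identifiers matched the GENCODE M21 annotation of GRCm38, from which symbols and positions were taken. A table of counts of the whole series was not used.

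Total counts ranged from 22814668 to 56916009 per library over 67 libraries. Intervals and spreads cover the mice sampled. Reads without molecular identifiers are not independent molecules, so counting error alone would be too small. No pair of libraries in a group agreed within sampling noise; the lowest chi-square per degree of freedom was 18.2.

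Counts were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test with robust estimation. One model with the 8 groups as terms was fitted to all 67 libraries, so that the groups shared one estimate of the spread. The groups did not vary equally. At day 8 the mean squared residual of a library was 0.128 to 0.176 in DKO control and 0.230 to 0.517 in DKO leucine-free livers. The shared estimate can therefore give too small a p in the noisier groups and too large a p in the tighter ones. The expression filter of edgeR kept 16908 genes and left out 38542. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and 12 comparisons were made. CPM values are counts divided by the TMM-scaled library size, and errors of log2 fold changes are standard errors (SE).

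Gene lists for pathways and for cell types that a piece of liver can hold, the rule for named genes and the design of the 12 comparisons were fixed before the data were examined. There were 35 lists, of which 34 had enough measured members. They were tested with cameraPR of limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Camera with a correlation estimated from the residuals was the alternative. Of 164 calls with the preset correlation, 17 held with the estimated one, and the p from the estimated correlation is given beside each list described. Counts of list members called are over all genes tested, and those adjusted over the list alone are named as such.

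The rule for named genes takes 20 genes named in advance, among them the sestrins, stress response and lipid genes. Some genes that the rule names are not reported here. The rule also takes, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall at a mean CPM of at least 5 in a compared group, leaving out predicted and clone names. The last part takes the 3 members with the smallest adjusted p of each called list. Genes of multi-copy families (Mup, Saa, Mt, Hba and Hbb, Gsta, Cyp3a41) are uncertain, since the counting may split reads among near-identical copies.

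The fit was tested on simulated counts with 200 changed genes among 16908. For the diet comparison in WT at day 1, 56.2% of the genes changed by a fold of 2 were recovered and 95.2% of those changed by a fold of 4. For the interaction of diet and genotype at day 8 these shares were 15.7% and 55.4%. False calls made up between 0% and 8.99% of calls over the 12 simulated comparisons, and the simulations were not repeated. In most of these comparisons, though not in all, the share lay above the threshold set for the adjusted p. The shares cannot show how the unequal spread of the groups affects the calls, since simulated counts need not carry that spread.

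The alternatives planned were DESeq2 1.42.0, limma with voom and quality weights, the older edgeR dispersion, DESeq2 size factors, total counts, no expression filter, a mean CPM of at least 1, only the compared groups, the mouse number as a block, 2 surrogate variables from sva 3.50.0, and each day 8 library left out in turn. A sex covariate was not run, because no library had more than 1 count over 4 Y-linked genes. The other alternatives were added after seeing the data. A model took the first 2 principal components of the clock genes as covariates, and another took the first 5 mice of each group. Others left out the library that has no Xist counts, or 3 libraries whose residual lay over 3 median absolute deviations above the median. These 3 libraries were WT leucine-free replicates 11 and 12 of day 1 and DKO leucine-free replicate 6 of day 8.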

Results

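The data are gene counts from 67 mouse livers. Sestrin1 and Sestrin2 are stress-induced proteins, and Sestrin2 binds leucine and restrains the growth kinase complex mTORC1 when leucine is scarce. The study compared WT with Sestrin DKO livers on control and leucine-free food. At day 1 there were 7 WT and 8 DKO livers on control food, and 12 WT and 18 DKO livers on leucine-free food. At day 8 there were 5 WT and 5 DKO livers on control food, and 6 WT and 6 DKO livers on leucine-free food. Total counts per library lay between 22814668 and 56916009.

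The targeted genes were examined first. Sesn1 (ENSMUSG00000038332, GRCm38 chromosome 10, 41809935 to 41908424) separated the genotypes without overlap, with 9.24 to 22.2 CPM in 30 WT libraries and 3.49 to 7.68 CPM in 37 DKO libraries. Its log2 difference, DKO minus WT, was -1.90 ± 0.11 (SE) on control food at day 1 and -1.42 ± 0.14 at day 8 (adjusted p = 2.51e-21 and 1.69e-11). Sesn2 (ENSMUSG00000028893, chromosome 4, 132492032 to 132510501), which the genotype label names, was not lower in DKO livers. It stood at 12.8 ± 1.57 CPM (SD, n = 7) in WT and 13.3 ± 2.40 CPM (n = 8) in DKO livers on control food at day 1. A count over the whole gene cannot show the loss of a part of it, so Sesn2 does not check the labels. Sesn3 (chromosome 9, 14275067 to 14333101) ranged from 21.1 to 54.3 CPM in WT and from 20.6 to 56.8 CPM in DKO libraries.

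**Figure D1:**
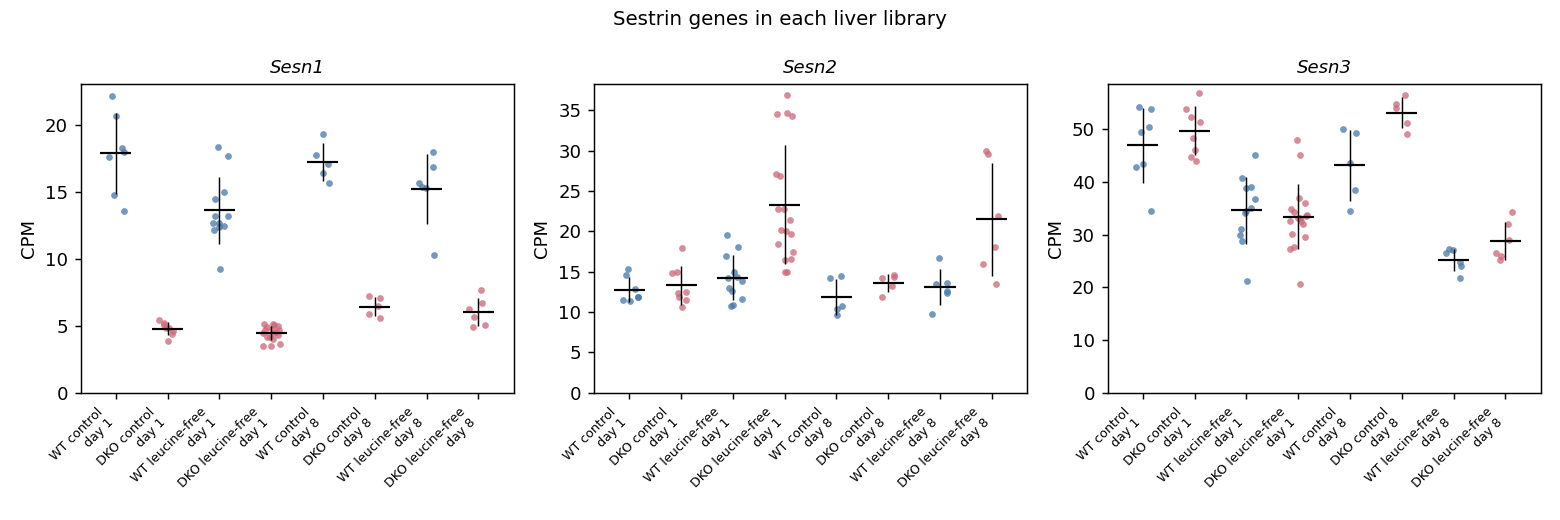
CPM of Sesn1, Sesn2 and Sesn3 in each library (points) by group, with the group mean (horizontal bar) and 1 SD (vertical line), WT in blue and DKO in red. Sesn1 lies between 9.24 and 22.2 CPM in WT and between 3.49 and 7.68 CPM in DKO libraries.

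In WT livers, 1 day without leucine lowered the genes of fat and cholesterol synthesis. Scd1, the stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879), fell from 9211 ± 4144 CPM (SD, n = 7) to 288 ± 256 CPM (n = 12), a log2 fold change of -5.00 ± 0.47 (adjusted p = 1.45e-12). Fasn, fatty acid synthase, fell by 3.50 ± 0.29 and Acss2, acetyl-CoA synthetase, by 3.65. Of 22 lipogenesis genes 19 fell (20 adjusted over the list alone) and none rose, with a median of -1.88 and adjusted p = 0.00016 with an estimated correlation. Of 25 cholesterol synthesis genes 24 fell (25 adjusted over the list alone, median -1.90, adjusted p = 0.0199 with an estimated correlation). Chrna4, a nicotinic acetylcholine receptor subunit, went from 98.0 ± 55.7 to 0.133 ± 0.160 CPM.

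Genes of fatty acid oxidation rose in part in these livers, with 12 of 28 higher and 1 lower (17 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.59 with an estimated correlation). The metallothioneins Mt2 and Mt1 rose by 5.14 ± 0.78 and 3.51 ± 0.55, and Pck1, of gluconeogenesis, by 1.32 ± 0.29. The pentose phosphate genes Taldo1, Pgd and Tkt, which stand on the NRF2 target list, fell by 0.81, fell by 1.94 and fell by 0.97 (8 of 18 on the list lower, 1 higher, adjusted p = 0.0329 with an estimated correlation). Cell cycle genes fell, 17 of 24 (median -1.17, adjusted p = 0.0316 with an estimated correlation). Fgf21, a hormone made by the liver under nutrient stress, was at 3.23 ± 2.19 CPM on control and 8.11 ± 6.65 CPM on leucine-free food (adjusted p = 0.101). In all, 3291 genes were called, 1400 higher and 1891 lower.

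Lipid synthesis genes also fell in DKO livers at day 1. Scd1 fell by 5.37 ± 0.40, 19 of 22 lipogenesis genes fell (19 adjusted over the list alone, median -1.77) and 23 of 25 cholesterol synthesis genes fell (24 adjusted over the list alone, median -1.86), with adjusted p = 0.000162 and 0.0235 with an estimated correlation. Genes of the integrated stress response, which is switched on by amino acid shortage, rose in part: 11 of 35 were higher and 2 lower (15 and 2 adjusted over the list alone, adjusted p = 0.396 with an estimated correlation). Fgf21 (chromosome 7, 45613886 to 45615490) rose from 4.00 ± 4.28 (SD, n = 8) to 38.8 ± 31.8 CPM (n = 18), a log2 fold change of 3.29 ± 0.56 (adjusted p = 6.09e-06). Trib3, a pseudokinase of this response, rose by 2.20 ± 0.42, Atf5 by 0.93 ± 0.16 and Sesn2 by 0.81 ± 0.14. The rise of Sesn2 is in counts over the whole gene, which cannot show whether its transcript is intact. Asns, asparagine synthetase, was at 5.18 ± 4.06 CPM on leucine-free food (adjusted p = 0.659). Of 15 endothelial markers 4 were higher and of 7 erythroid markers 3 were lower (adjusted p = 0.52 and 0.472 with an estimated correlation).

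Glucocorticoid-responsive genes rose in DKO livers at day 1, 11 of 15 (13 adjusted over the list alone, median 1.52, adjusted p = 0.038 with an estimated correlation), with Mt2 at 6.05 ± 0.76 and Sgk1 at 1.99 ± 0.41. Of 19 acute phase genes 15 were higher (median 0.95, adjusted p = 0.472 with an estimated correlation); Saa1 reached 535 ± 1620 CPM, an SD above its mean. In WT livers 5 of the 15 and 4 of the 19 were higher, with none lower (adjusted p = 0.59 and 0.898 with an estimated correlation), and for the interaction of diet and genotype at day 1 this was 1 of 15 and 0 of 19 (adjusted p = 0.317 and 0.986 with an estimated correlation). Of 24 cell cycle genes 22 fell (23 adjusted over the list alone, median -3.20, adjusted p = 7.15e-06 with an estimated correlation), with Ccnb1, cyclin B1, down from 5.66 ± 3.39 to 0.133 ± 0.116 CPM. In all, 3976 genes were called, 1772 higher and 2204 lower, and 1924 with the first 5 mice per group. Across genes, which are not independent replicates, the diet responses of the genotypes at day 1 correlated with r = 0.705. They shared 879 higher genes, against 146.7 for independent lists, and 1364 lower genes, against 246.5, and no gene was called in opposite directions. The groups share no libraries.

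**Figure D2:**
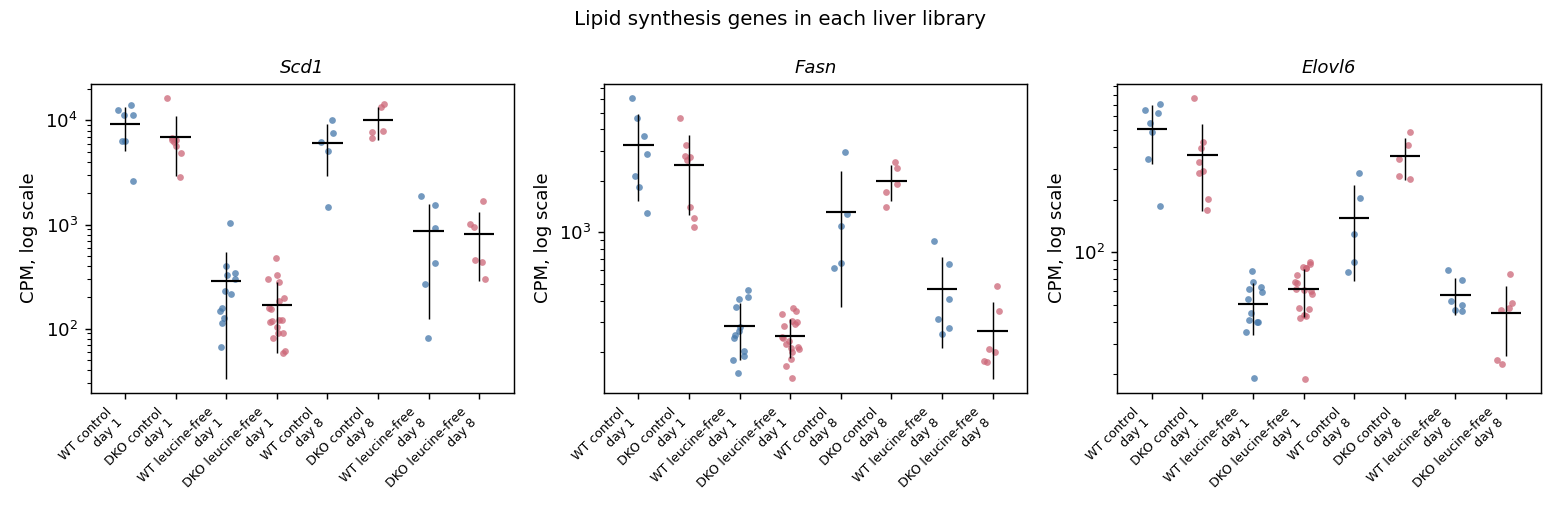
CPM (log scale) of Scd1, Fasn and Elovl6 in each library (points) by group, with the mean (horizontal bar) and 1 SD (vertical line, its lower end limited to 0.5 of the lowest value), WT in blue and DKO in red. Mean Scd1 goes from 9211 to 288 CPM in WT and from 6996 to 170 CPM in DKO livers at day 1.

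Whether loss of the sestrins changes the fed liver was asked on control food. At day 1 genes of cell division were among those that differed. Of 24 cell cycle genes 17 were higher in DKO livers and none lower (20 adjusted over the list alone, median 2.03, adjusted p = 2.81e-08 with an estimated correlation). Ccnb1 (chromosome 13, 100778650 to 100786570) was at 0.634 ± 0.276 CPM (SD, n = 7) in WT and 5.66 ± 3.39 CPM (n = 8) in DKO livers, a log2 difference of 3.14 ± 0.30 (adjusted p = 5.17e-13). Cenpf, a kinetochore protein, was higher by 3.30 ± 0.33, Hmmr by 2.89 ± 0.29 and the mitotic kinases Plk1 and Aurkb by 2.59 and 2.37. These are low levels. By the mean of the list, 7 of the 8 DKO libraries lay above every WT library, and DKO replicate 5, at a mean log2 CPM of 1.74, lay below WT replicate 7, at 1.97. The medians of the macrophage, lymphocyte and neutrophil marker lists differed by 0.035, 0.065 and 0.185. In all, 142 genes were higher and 7 lower, and with a mean CPM of at least 1 the count was 53. The cell cycle difference was not seen in the controls of day 8, where none of the 24 genes was called (median 0.12, adjusted p = 0.942 with an estimated correlation) and the mean log2 CPM of the list lay between 0.291 and 0.878 in WT and between 0.449 and 1.12 in DKO libraries.

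At day 8 on control food 9 genes were called, 8 higher in DKO livers and 1, Sesn1, lower. Chrna4 was higher by 2.23 ± 0.42, Raet1d by 2.20 ± 0.47, Pdzk1ip1 by 1.78 ± 0.30, G6pdx, an enzyme of the pentose phosphate pathway, by 1.41 ± 0.28, and Dlat, of the pyruvate dehydrogenase complex, by 0.66 ± 0.12. Chrna4 was not called without WT replicate 2, Dlat without WT replicates 2 or 4 or DKO replicate 4, G6pdx without WT replicates 2, 4 or 5 or DKO replicate 4, and Raet1d without any 1 of the WT replicates or DKO replicates 3, 4 and 5 (adjusted p from 0.0505 to 0.229). The lipogenesis list had a median of 0.67, with none of 22 genes called over all genes tested and 9 higher adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). The count was 2 without WT control replicate 2, 4 without WT control replicate 4 or DKO control replicate 4, 5 without WT control replicate 5 and 14 without DKO control replicate 3. It was 92 with voom and 8 with DESeq2.

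**Figure D3:**
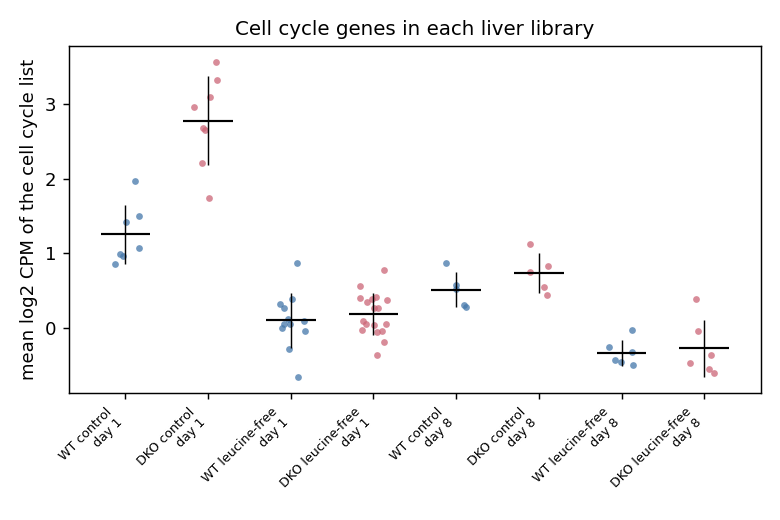
Mean log2 CPM of the 24 cell cycle genes in each library (points) by group, with the group mean (horizontal bar) and 1 SD (vertical line), WT in blue and DKO in red. On control food at day 1, 7 of 8 DKO libraries lie above every WT library.

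On leucine-free food at day 1, 10 of 35 integrated stress response genes were higher in DKO than in WT livers and none lower (14 higher and 1 lower adjusted over the list alone, median 0.22, adjusted p = 0.0907 with an estimated correlation). Fgf21 was higher by 2.24 ± 0.44 (adjusted p = 0.00148), at 38.8 ± 31.8 CPM (SD, n = 18) against 8.11 ± 6.65 CPM (n = 12). Ddit4, an inhibitor of mTORC1 (chromosome 10, 59949669 to 59951834), was higher by 3.12 ± 0.49, Atf3 by 1.84 ± 0.35, Trib3 by 1.37 ± 0.34, Sesn2 by 0.72 ± 0.12 and the leucine transporter gene Slc7a5 by 0.93 ± 0.15. Sesn2 is the gene that the genotype label names, so its count in DKO livers may not stand for an intact transcript. Tat, tyrosine aminotransferase, was higher by 1.05 ± 0.22. Cyp1a1, a xenobiotic-metabolising enzyme, was at 52.0 ± 149 CPM in WT and 1.63 ± 3.90 CPM in DKO livers, but WT replicates 4 and 5 held 515 and 101 CPM and the other 10 WT libraries lay between 0.26 and 1.13 CPM, so those 2 libraries carry the difference. The clock gene Dbp was lower by 1.93 ± 0.57, and ranged from 1.25 to 131 CPM within the WT group. Of 7 erythroid markers 3 were lower (list median -0.84, adjusted p = 0.384 with an estimated correlation). In all, 625 genes were called, 316 higher and 309 lower. With total counts in place of TMM 70.54% of calls were higher, against 50.56%. The count was 284 with only these groups and 1419 without the 3 libraries of high residual. WT replicates 2, 4, 5 and 12 and DKO replicates 1 and 16 had the highest shares of rRNA counts, from 0.4065% to 0.4771%. Whether this difference between libraries enters the calls was not tested.

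The test of whether the genotypes responded differently to the diet at day 1 called 63 genes, 62 of them with a more negative log2 response in DKO livers. Of the 63, 58 moved the same way in both genotypes and further in DKO livers, and 5, Ddit4 among them, had estimated responses of opposite sign. Among those 62 were 12 of 24 cell cycle genes (20 adjusted over the list alone, median -1.68, adjusted p = 7.03e-06 with an estimated correlation), with Ccnb2 at -3.13 ± 0.52 and Birc5 at -2.47 ± 0.41. The level on control food enters this difference. Ddit4 was the 1 gene in the other direction, at 3.26 ± 0.75 (adjusted p = 0.0204). Fgf21, at 1.95 ± 0.77, did not pass (adjusted p = 0.631), and the stress response list had a median of 0.39 (adjusted p = 0.0725 with an estimated correlation). The count was 29 with voom and 12 with the first 5 mice per group.

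**Figure D4:**
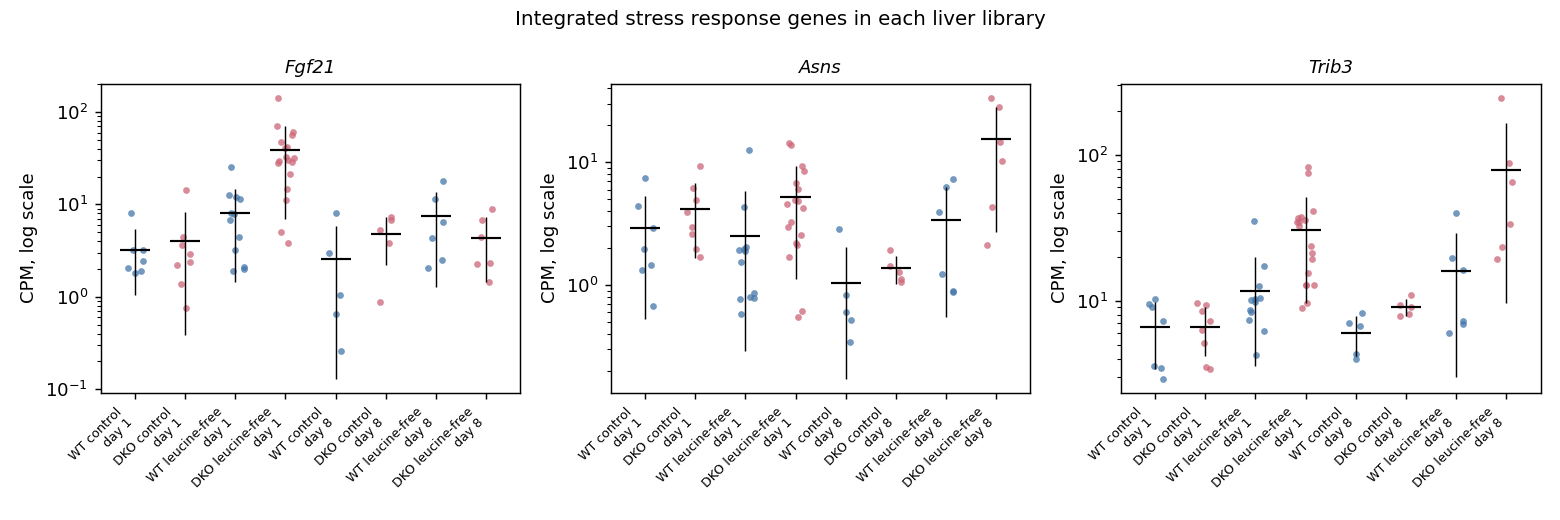
CPM (log scale) of Fgf21, Asns and Trib3 in each library (points) by group, with the mean (horizontal bar) and 1 SD (vertical line, its lower end limited to 0.5 of the lowest value), WT in blue and DKO in red. Mean Fgf21 is 38.8 CPM in DKO livers on leucine-free food at day 1 and 4.38 CPM at day 8.

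After 8 days without leucine, WT livers had higher ribosomal protein genes and lower interferon-responsive genes. Of 46 ribosomal protein and elongation factor genes 38 rose (44 adjusted over the list alone, median 0.38, adjusted p = 0.0602 with an estimated correlation), with Eef2 at 0.53 ± 0.08. Of 20 interferon-responsive genes 17 fell (19 adjusted over the list alone, median -0.89, adjusted p = 0.0153 with an estimated correlation), such as Ifit1, from 15.5 ± 2.52 (SD, n = 5) to 4.48 ± 1.39 CPM (n = 6). Of 15 macrophage markers 4 fell, Clec4f by 0.79 ± 0.22 and Timd4 by 0.94 ± 0.27 (list median -0.66, adjusted p = 0.316 with an estimated correlation). Both lost their call without WT control replicate 2 or 3 or WT leucine-free replicate 3, and Clec4f also without WT leucine-free replicate 1 (adjusted p from 0.0504 to 0.0716). Of 15 lymphocyte, 7 erythroid, 15 stellate and 9 neutrophil markers 3, 1, 1 and 2 fell (adjusted p = 0.227, 0.33, 0.797 and 0.807 with an estimated correlation). Lipogenesis genes fell, 13 of 22 (median -0.96, adjusted p = 0.0862 with an estimated correlation), Scd1 by 2.83 ± 0.59. The cholesterol synthesis list had a median of -0.48 (adjusted p = 0.655 with an estimated correlation). The WT libraries of day 8 all had Xist counts and no Y-linked counts, as in female mice. Of 11 genes known to be higher in male livers 3 fell in them (list adjusted p = 0.43 with an estimated correlation). Among these were Slco1a1, which fell by 5.24 ± 0.96, and Hsd3b5, which fell by 5.93 ± 1.64. Without WT control replicate 1 the log2 fold changes were -3.28 and -2.81, the latter not called (adjusted p = 0.54), and Hsd3b5 was also not called without WT leucine-free replicate 2 (adjusted p = 0.0512). In all, 888 genes were called, 402 higher and 486 lower. The count was 568 without WT leucine-free replicate 3, 1929 with voom and 1595 with only these groups. Dbp fell by 3.91 ± 1.13 and lost its call without any 1 of WT control replicates 3 and 5 and WT leucine-free replicates 1, 2, 3, 4 and 6 (adjusted p from 0.0518 to 0.134).

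In DKO livers at day 8 all 46 ribosomal protein genes rose (median 0.77, adjusted p = 0.00541 with an estimated correlation), such as Rps6, from 91.0 ± 6.62 (SD, n = 5) to 173 ± 26.6 CPM (n = 6). Of 20 interferon-responsive genes 19 fell (median -1.13, adjusted p = 0.0243 with an estimated correlation), with Irf7 at -1.37 ± 0.18, and 11 of 15 macrophage markers fell (median -0.71, adjusted p = 0.401 with an estimated correlation), as did 3 of 7 erythroid markers (adjusted p = 0.281 with an estimated correlation). Of 15 stellate markers 3 fell and 1 rose, and of 15 lymphocyte markers 1 fell (adjusted p = 0.71 and 0.612 with an estimated correlation). Lipogenesis genes fell, 17 of 22 (median -2.08, adjusted p = 0.00541 with an estimated correlation), as did 20 of 25 cholesterol synthesis genes (median -1.40, adjusted p = 0.191 with an estimated correlation). Of the stress response list 13 of 35 rose and 1 fell (adjusted p = 0.191 with an estimated correlation), Asns (chromosome 6, 7675169 to 7693254) by 3.48 ± 0.73, Trib3 by 3.13 ± 0.58 and Psat1, of serine synthesis, by 2.72 ± 0.51. Without DKO leucine-free replicate 6 Trib3 rose by 2.335 and Psat1 by 1.94, both still called. Fgf21 was at 4.80 ± 2.58 and 4.38 ± 2.94 CPM (adjusted p = 0.946). Ghr, the growth hormone receptor, fell by 1.03 ± 0.14 and Igf1 by 0.84 ± 0.18. In all, 3482 genes were called, 1874 higher and 1608 lower. The count was 2674 without DKO control replicate 5. With only the groups compared it was 2424 in DKO and 1595 in WT livers, so the gap between the genotypes depends on the shared fit. Across genes the responses of the genotypes at day 8 correlated with r = 0.519, and 304 higher and 355 lower genes were shared, against 44.56 and 46.22 for independent lists.

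Between genotypes on leucine-free food at day 8, DKO livers had higher Trib3 by 2.32 ± 0.52 (adjusted p = 0.00778), Asns by 2.21 ± 0.63 and Psat1 by 1.99 ± 0.46. DKO leucine-free replicate 6, 1 of the 3 libraries of high residual, held 246 CPM of Trib3 where the next library held 87.4. Without it the differences were 1.525, 1.82 and 1.21, and none of the 3 genes was called (adjusted p = 0.104, 0.157 and 0.17). Asns was also not called without WT leucine-free replicates 1, 2, 3 or 6 or DKO leucine-free replicates 2 or 3 (adjusted p from 0.057 to 0.133). Of 35 stress response genes 5 were higher and 1 lower (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Of 46 ribosomal protein genes 20 were higher (44 adjusted over the list alone, median 0.29, adjusted p = 0.213 with an estimated correlation), and of 15 endothelial markers 1 was higher (adjusted p = 0.679 with an estimated correlation). Of 28 fatty acid oxidation genes 4 were lower (adjusted p = 0.585 with an estimated correlation), among them Fabp1, the liver fatty acid binding protein, by 1.04 ± 0.27 (not called without WT leucine-free replicate 3 or DKO leucine-free replicates 2 or 6, adjusted p from 0.0643 to 0.0821), and Car3, carbonic anhydrase 3, went from 1254 ± 381 to 233 ± 128 CPM. In all, 349 genes were called, 244 higher and 105 lower. The count was 107 with only these groups, 163, 189 and 203 without WT leucine-free replicates 1, 3 and 4, and 587, 164 and 198 without DKO leucine-free replicates 1, 2 and 6.

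The interaction of diet and genotype at day 8 called 7 genes, and 1506 had an unadjusted p under 0.05. Of the 7, 5 had estimated responses of opposite sign in the genotypes and 2 moved the same way and further in DKO livers. Eif4ebp3 stood at 2.97 ± 0.63 and Gfra1 at 1.09 ± 0.22 on the side of a higher response in DKO livers, and Rdh16, a retinol dehydrogenase, at -1.89 ± 0.37 and Muc1 at -2.22 ± 0.47 on the other. Of 46 ribosomal protein genes none was called over all genes tested and 44 were higher adjusted over the list alone (adjusted p = 0.121 with an estimated correlation). Of 11 cholangiocyte markers 1, Muc1, was called (list adjusted p = 0.121 with an estimated correlation). With edgeR the count was 0 without WT control replicate 2, DKO control replicate 1, WT leucine-free replicate 1 or 3 or DKO leucine-free replicate 2, and between 1 and 4 without WT control replicate 1, DKO control replicates 3 and 5, WT leucine-free replicates 4 and 6 or DKO leucine-free replicate 6. It was 38 without WT control replicate 5, 15 without WT leucine-free replicate 2, and 24, 14, 19 and 25 without DKO leucine-free replicates 1, 3, 4 and 5, against 60 with DESeq2 and 89 with voom on all libraries.

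Between day 1 and day 8 the response to the diet changed in WT livers for 278 genes, 146 toward higher and 132 toward lower values. Estimated responses had opposite signs on the days for 188 of them. Of the rest, 73 moved further at day 1 and 17 further at day 8. A sign can differ where a response is near 0. Over all genes tested, 7 were called on both days in opposite directions. Some genes of lipid synthesis had a smaller fall at day 8: 6 of 25 cholesterol synthesis genes (25 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation) and 9 of 22 lipogenesis genes (median 1.16, adjusted p = 0.0583 with an estimated correlation), with Fasn at 2.00 ± 0.46 (not called without WT control replicate 4 or WT leucine-free replicate 1, adjusted p = 0.0507 and 0.0597). The level on control food enters this, since mean Fasn went from 3232 CPM at day 1 to 1320 CPM at day 8 in WT controls and from 285 to 465 CPM in WT leucine-free livers. Mt2 moved the other way, at -4.49 ± 1.02. Of the cell type markers 1 of 15 for lymphocytes and 2 of 9 for neutrophils went toward lower values, and of 15 for stellate cells 1 went each way (adjusted p = 0.195, 0.561 and 0.656 with an estimated correlation). The count was 134, 121 and 179 without WT control replicates 2, 4 and 5, and 104 and 167 without WT leucine-free replicates 1 and 3. In DKO livers 1494 genes differed, 894 toward higher and 600 toward lower values. Here the signs of the estimated responses were opposite for 1028, while 109 moved further at day 1 and 357 further at day 8. Over all genes tested, 71 were called on both days in opposite directions. Of 46 ribosomal protein genes 43 were higher (median 0.60, adjusted p = 0.029 with an estimated correlation) and 16 of 24 cell cycle genes had a smaller fall (median 1.65, adjusted p = 0.0133 with an estimated correlation). The level on control food enters this, since the mean log2 CPM of the list lay between 1.74 and 3.56 in DKO controls at day 1 and between 0.449 and 1.12 at day 8. Toward lower values went 10 of 15 macrophage, 2 of 15 endothelial, 1 of 11 cholangiocyte and 1 of 15 lymphocyte markers (adjusted p = 0.272, 0.583, 0.583 and 0.527 with an estimated correlation). Fgf21 moved by -3.39 ± 0.90 and Asns by 3.14 ± 0.85 (adjusted p = 0.00972 and 0.0122). Saa2 and Saa1 stood at -6.20 ± 1.82 and -5.23 ± 1.62, and Saa1 was not called without DKO leucine-free replicates 2 or 3 of day 8 (adjusted p = 0.0523 and 0.0506). The count was 763 with the first 5 mice per group.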

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

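The tests of immune cells and of a few or a single DKO library for the cell cycle genes, and those of collection time for the day 8 response, were chosen after the result was seen. The clock covariates themselves were added after the data were seen, while the splits of the samples and the other tests of causes in this section were fixed before their results.

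Of 120 group values examined for a single distant library, 17 were found. Chance alone gives about 1 in 20 only for normally distributed values. CPM was not transformed here, and a long upper tail would raise that rate. Apart from Sesn1, the flagged values stood on the high side. Groups of more than 10 libraries, the 12 WT and 18 DKO leucine-free livers of day 1, were not examined. On control food at day 1, Fgf21 stood apart at 8.01 CPM in WT replicate 5 and at 14.2 CPM in DKO replicate 5, and Ddit3 at 19.4 CPM in DKO replicate 1. DKO replicate 3 of that group stood apart for Gdf15 at 18.3 CPM, Scd1 at 16500 CPM and Elovl6 at 768 CPM. Among WT control livers at day 8, replicate 4 stood apart for Asns at 2.84 CPM, Gdf15 at 13.5 CPM and Pck1 at 3570 CPM, replicate 1 for Chac1 at 7.48 CPM and replicate 3 for Fasn at 2950 CPM. Chac1 stood at 10.2 CPM in DKO control replicate 2 at day 8. On leucine-free food at day 8, Sesn1 stood low at 10.3 CPM in WT replicate 4 and Igfbp1 high at 322 CPM in WT replicate 5. In the DKO livers of that diet and day, Trib3 stood apart at 246 CPM in replicate 6, Srebf1 at 413 CPM in replicate 1 and Ppargc1a at 85.2 CPM in replicate 5.

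Effects that differed between groups by a test of the difference itself were the 63 and 7 genes with an interaction of diet and genotype at day 1 and day 8, and the 278 and 1494 genes whose diet response changed between the days in WT and DKO livers. Among genes named in advance, the response changed between days for Fasn by 2.00 (not called without WT control replicate 4 or WT leucine-free replicate 1 of day 8, adjusted p = 0.0507 and 0.0597) and Elovl6 by 1.89 in WT livers, and for Fgf21 by -3.39, Asns by 3.14 and Srebf1 by 1.38 in DKO livers. The level on control food enters these values. Between the days mean Elovl6 went from 508 to 156 CPM in WT controls and from 50.3 to 57.3 CPM in WT leucine-free livers, and mean Fasn from 3232 to 1320 CPM and from 285 to 465 CPM. In DKO livers mean Srebf1 went from 539 to 332 CPM in controls and from 166.1 to 266.5 CPM on leucine-free food, Asns from 4.20 to 1.37 CPM and from 5.18 to 15.5 CPM, and Fgf21 from 4.00 to 4.80 CPM and from 38.8 to 4.38 CPM.

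For each comparison 100 splits of the compared libraries, the real one included, were fitted on those libraries alone, and 1 of 100, the real split, gave as many calls in each of the 12. A share of 1 of 100 is the lowest that 100 splits can give. It argues against chance as the source of the diet and genotype counts but does not exclude it. For the interactions, labels of genotype or day were moved within a diet. This also breaks the differences of genotype or day themselves, so these splits cannot decide on the interaction. The real count and the highest of the other splits were 2627 and 6 for the diet in WT at day 1, 3671 and 654 in DKO at day 1, 1595 and 357 in WT at day 8, and 2424 and 1 in DKO at day 8. For the genotypes they were 104 and 5 on control and 284 and 279 on leucine-free food at day 1, and 10 and 2 on control and 107 and 2 on leucine-free food at day 8. For the interaction of diet and genotype they were 52 and 3 at day 1 and 3 and 2 at day 8, and for diet and day 217 and 11 in WT and 1222 and 5 in DKO livers. The margin was narrow for the genotypes on leucine-free food at day 1 and for the interaction at day 8.

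Cell cycle genes were higher in DKO than in WT livers on control food at day 1, with a list median of 2.03. Immune cells in the tissue would raise their own markers, but the highest median of 3 immune lists was 0.185. Collection time is argued against, since the median kept 101% of its value under the clock covariates, and a single DKO library is argued against, since the lowest median without any 1 of them kept 91.1%. A few DKO libraries are argued against as the whole source, since the median kept 72.8% of its value without the 3 highest of them, and 7 of 8 DKO libraries lay above every WT library. In the controls of day 8 the list was not called (median 0.12), and whether the genotype difference changed between the days was not tested. An effect of genotype may account for the pattern at day 1 as a hypothesis, and age and litter, which were not tested, stay open.

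The diet response at day 8 coincided with a difference in clock genes, since Dbp lay between 0.512 and 2.92 CPM in all 12 leucine-free livers and between 0.871 and 52.0 CPM in WT controls and between 1.25 and 18.1 CPM in DKO controls. Under the clock covariates 73.8% of the genes called in DKO livers were called again in the same direction, and the genes kept a median of 98.2% of their log2 fold change (quartiles 84.5% and 112%). In WT livers 414 of 888 genes (46.6%) were called again and 259 others were called, a share that does not decide by itself. The 888 genes kept a median of 93% of their log2 fold change (quartiles 79.1% and 109%), while their SE changed by a median of 1.12 times. These folds argue against collection time, as far as the covariates follow it, as the main source in both genotypes. A smaller part stays open, since diet and clock genes vary together here, and a change of feeding rhythm by the diet, which would shift the same genes, was not tested.

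Of 35 stress response genes 10 were higher in DKO than in WT livers on leucine-free food at day 1, with a list median of 0.22 and adjusted p = 0.0907 with an estimated correlation, so the list as a whole was not called that way. The lowest median without any 1 DKO library kept 82.3% of its value, which argues against a single library. Under the clock covariates the median kept 72.2%, which argues against collection time as the whole source. The median is small beside Ddit4 and Fgf21, and an effect of genotype on this response may be a hypothesis for those genes. Ddit4 also stands on the list of glucocorticoid-responsive genes, and which response its difference reflects was not tested. Litter, age and the differing shares of rRNA counts were not tested.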

How the results depend on the processing

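The clock covariates, the first 5 mice per group and the fits without the 3 libraries of high residual or without the Xist-negative library were chosen after seeing the data. No named gene turned direction under the alternatives fixed beforehand, and calls were lost for 5 of 394 with DESeq2, 43 of 398 with voom, 14 with total counts, 54 with no expression filter and 74 of 391 with only the groups compared. The clock covariates lost 66 calls, and the first 5 mice lost 103. Dbp in WT at day 8 went to 0.25 under the clock covariates, which are built from Dbp and other clock genes, so this value says nothing of its direction. A sex covariate was not run. Of 5082 values of named genes with a day 8 library left out, 360 lost their call and none turned. Many of these fits left out a library of a group not compared, so this share does not measure dependence on the compared libraries alone. In each sentence below the cause was not tested, unless fewer mice or genes give it.

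For the diet in DKO at day 1 the count was 1924 with the first 5 mice, against 3976. For the genotypes on control food at day 1 it was 53 with a mean CPM of at least 1, since fewer low genes were tested, against 149. On leucine-free food at day 1, against 625, it was 1224 with voom, 298 with no filter, 284 with only the groups compared, 958 with surrogate variables and 1419 without the 3 libraries of high residual. For the interaction at day 1, against 63, it was 29 with voom, 36 with a mean CPM of at least 1 and 12 with the first 5 mice.

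For the diet in WT at day 8, against 888, it was 1929 with voom, 501 with no filter and 1595 with only the groups compared, and from 568 to 1001 with 1 library left out. The 1001 came without DKO leucine-free replicate 6, of a group not compared. Without a compared library the count was at most 744. For the genotypes on control food at day 8, against 9, it was 92 with voom, 4 with the older dispersion, 23 with surrogate variables, 3 with the first 5 mice and from 2 to 14 with 1 library left out. On leucine-free food at day 8, against 349, it was 217 with no filter, 107 with only the groups compared, 212 with the clock covariates, 187 with the first 5 mice and from 163 to 587 with 1 library left out. For the interaction at day 8, against 7, it was 60 with DESeq2, 89 with voom, 2 with the older dispersion, 0 with no filter, 12 with a mean CPM of at least 1, 3 with only the groups compared, 46 with surrogate variables, 4 without the libraries of high residual, 11 with the clock covariates, 2 with the first 5 mice and from 0 to 38 with 1 library left out. For diet and day in WT, against 278, it was 625 with voom, 140 with no filter and from 104 to 280 with 1 library left out. In DKO, against 1494, it was 953 with no filter and 763 with the first 5 mice. Other counts of the 12 comparisons lay within 1.5 times, apart from the 2 below with the mouse number as a block.

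Mice share numbers in the labels, and same-numbered livers deviated together weakly if at all (mean correlation from -0.02 to 0.086). At day 1 the closest liver had the same number in 3 of 7 pairs across the WT diets and 0 of 8 across the DKO diets. Across the genotypes this was 2 of 7 on control and 1 of 12 on leucine-free food. No reference with shuffled numbers was made, so handling shared by number is not excluded. The main model did not pair the mice. With the number as a block the count was 1387 for the diet in WT at day 8 and 603 for diet and day in WT.

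Of 164 list calls 17 held with an estimated correlation. The lists that turned direction, by their median log2 value, were stellate (0.017) and neutrophil markers (0.124) for the diet in WT at day 8 and acute phase genes for diet and day in WT (0.073) with surrogate variables. Without the libraries of high residual, ribosome biogenesis (-0.011) and NRF2 targets (0.031) turned for the genotypes on leucine-free food at day 8. With the first 5 mice, the NRF2 list (0.037) turned there, cholesterol synthesis (0.098) for the genotypes on leucine-free food at day 1, and the unfolded protein (0.016) and cholangiocyte (0.016) lists for the interaction at day 1. A median can keep its sign where the test turns. Depth limits low genes such as those of the cell cycle.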

Other observations

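The test of a single X chromosome was chosen after the values of its genes were seen, and the test of other X-linked genes before.

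Of 18 genes on the NRF2 list 6 changed their diet response between the days toward higher and none toward lower values in DKO livers, and the list was not called with an estimated correlation (adjusted p = 0.432). Tkt, of the pentose phosphate pathway, had a change of response of 0.67 ± 0.14 (SE), and Gstm3, of a family with near-identical copies, of 2.20 ± 0.45 (1.56 without DKO leucine-free replicate 6 of day 8). Of 20 genes of aminoacyl-tRNA synthesis, which load amino acids on tRNA, 11 fell with the diet in WT livers at day 1, Cars by 0.72 ± 0.13 (list adjusted p = 0.225 with an estimated correlation). Their diet response changed toward higher values by day 8 for 4 of 20 in WT livers and 7 of 20 in DKO livers, Vars in DKO by 0.71 ± 0.11 (list adjusted p = 0.137 and 0.24 with an estimated correlation).

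The vomeronasal receptor gene Vmn2r3 was at 9.16 ± 16.2 CPM (SD, n = 6; 2.61 CPM without replicate 6, at 41.9 CPM) in DKO livers on leucine-free food at day 8 and at 0 counts in the 5 DKO livers on control food, so that no fold is given. At day 1 on leucine-free food, a value chosen after it was seen, it was at 0.672 ± 0.701 CPM (n = 18) in DKO livers.

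One library, DKO leucine-free replicate 1 at day 1, had 0 Xist counts and 0 counts over 4 Y-linked genes, whereas every other library had Xist counts. A single X chromosome in that mouse is a candidate explanation. It predicts lower levels of genes that escape X inactivation, and the median log2 difference of Kdm6a, Kdm5c, Eif2s3x and Ddx3x from the other libraries of its group was -0.563, against a lowest value of -0.181 among those libraries. Ddx3x alone stood at -0.097. If both X chromosomes were active, other X-linked genes would be higher, but the median of 482 such genes was 0.034, within the range from -0.068 to 0.058 of the other libraries. The karyotype was not tested.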
